A study of Mus musculus with 24 samples.

How the data were processed

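Whole-blood RNA of 24 male 129S/J mice was measured on 1-colour Agilent mouse expression arrays, 1 mouse per array per the labels and the series design. The mice were wild type or lacked Parp1, and were killed 24 h after X-ray or sham exposure. Blood was taken from the heart into an RNA stabiliser, RNA was purified on columns with DNase and globin RNA was removed, per the labels' protocols. Samples were grouped by the genotype and dose in their labels into wild-type 0 Gy (n = 5), wild-type 6 Gy (n = 5), wild-type 8.8 Gy (n = 4), knockout 0 Gy (n = 5) and knockout 6 Gy (n = 5), and no sample was left without a group.

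The deposited scanner files hold spot intensities on a linear scale, 1 file per array. Per the file headers, they were made with Agilent Feature Extraction 11.5.1, which subtracts the background and detrends within the array and does not normalise between arrays. The submitters' processing notes name the same program. The authors' table of the whole series holds log2 values. Set against the scanner values, each of its columns equalled the log2 processed signal plus 1 constant per array over 10214 probes, with 8376 cells empty. Scale and direction were therefore settled, whereas how the constants, the probes and the empty cells were chosen is not given in the sources used here. The column medians of that deposited log2 table were 7.94, 7.68, 7.73, 7.66 and 7.80 for wild-type 0 Gy replicates 1 to 5, 7.75, 7.86, 7.76, 7.65 and 7.70 for wild-type 6 Gy, and 7.71, 7.85, 8.04 and 7.97 for wild-type 8.8 Gy replicates 1 to 4. They were 8.09, 7.66, 8.01, 7.69 and 7.63 for knockout 0 Gy and 7.83, 7.70, 8.06, 7.88 and 7.86 for knockout 6 Gy.

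Each array has 44397 spots, of which 43020 are not controls. Control spots and spots with an outlier mark of the extraction program were left out, and saturated spots were kept. The processed signal was taken to log2 and each array's 75th percentile over the non-control spots was subtracted. Spots of 1 probe were averaged, which gave 39429 probes. A probe was named through its RefSeq accession in the RefSeq gene table of assembly GRCm38.p6 (27508 probes) or else by the name in the array file (5645 probes), and 6276 probes had no symbol. Coordinates are those of the array files, which name mm9. Of several probes of a symbol the one with the highest mean over the 24 arrays stood for the gene. Probes of 1 gene were called in opposite directions for 33 genes in the wild-type 6 Gy response, 11 in the knockout response and 0 in each of the other comparisons. A gene was tested if its probe was well above background on at least 4 arrays of at least 1 group, which left 13023 of 24232 symbols. Of these, 7576 were detected on all 24 arrays, and 9535 probes of the design were well above background on no array. The precision is limited by the number of arrays.

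The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings) on a model of the 5 group means over all 24 arrays, so that the groups shared 1 estimate of the spread. Every adjusted p in the text is from limma, or from limma's camera for gene lists, unless an exact test is named, and all tests were two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. There were 9 comparisons: each irradiated group against the sham group of its genotype, the genotypes at 0 Gy, at 6 Gy and at the dose lethal to 50% within 30 days, both doses in wild type, and 2 interactions that compare the knockout response with each wild-type response. SE stands for the moderated standard error of a log2 difference. A probe not well above background on any array of a group has only a bound there. Such a change is given as at least N-fold, the brighter group's mean against the mean, over the dimmer group's arrays, of the higher of the lowest signal well above background and the probe's own. An interaction with such a group is given no size, and its values under alternatives give the direction only.

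Gene lists (27, for blood cell types, DNA repair, p53, interferon, poly(ADP-ribose) and NAD metabolism, and housekeeping groups) were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. List scores of arrays were also fitted with scan day by an ordinary linear model. The same test with the correlation estimated per list is given beside it. Lists of fewer than 3 measured members would not have been tested, and all 27 had more. Members that passed are counted over all genes tested and adjusted over the list alone. Array quality (share of probes well above background, 75th percentile, globin level) was compared between groups with exact permutation tests, adjusted over the 30 planned tests. Marker lists of liver, heart muscle, skeletal muscle, lung and Kupffer cells were written after the data were examined.

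Parp1 is given first in every array. The named genes are, per comparison, the 6 with the largest rise and the 6 with the largest fall among those past the threshold whose values in the groups compared did not overlap in any array, without provisional symbols, and with no overlap condition for interactions. Added to these are the 2 members of each gene list described that had the smallest adjusted p, whether or not they passed. For lists given in less detail this was narrowed, after the values were seen, to 1 member, and in the interactions to members that passed. A gene named in 1 comparison may be given in another. Counts of named genes are over all genes so picked, some of which the text leaves out. This rule, the gene lists, the groups, the tests and most alternatives were fixed before the data were examined.

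Slide (10) and scan day (4) were read from the array files and used as a fixed and as a random block (duplicateCorrelation). Other alternatives were quantile normalisation, median centring, the 75th percentile over probes detected on all arrays, normexp (offset 50) on the mean and local background signals, the authors' log2 table, no filter on dim probes, only probes detected on all 24 arrays, every probe tested separately, the mean of a gene's probes, outlier spots kept, an intensity trend with a robust prior, array weights, an ordinary linear model, only the groups compared in the fit, a minimum absolute log2 change of 1, the replicate number as a block, list members that another list also holds left out, and each array left out in turn. Alternatives added after the data were seen left out local dim patches (windows of 10 rows and 3 columns on each side, with at least 8 bright spots, whose median lay over 1 log2 unit from the 24-array median), used the hepatocyte marker score as a covariate, left out arrays in doubt, or used only arrays of scan day 3. Bright spots were those well above background on at least 20 arrays. For overlaps of comparisons with the same sham arrays, 100 simulations of unchanged groups were drawn, and 100 splits of the samples were drawn per comparison, with seed 20.

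Simulations tested the steps, with 200 of 13023 genes changed on values with the real spread. At a change of 2 log2 units the test recovered 79% of 100 genes for wild-type 6 Gy against 0 Gy, 75% for wild-type 8.8 Gy, 76% for knockout 6 Gy against 0 Gy, 85% and 80% for the genotypes at 0 Gy and 6 Gy, 77% for knockout 6 Gy against wild-type 8.8 Gy, and 69% for the wild-type doses. The interactions gave 45% at equal dose and 41% at equal lethality. At a change of 1 log2 unit it recovered 24%, 19%, 32%, 28%, 21%, 22%, 22%, 4% and 3% in the same order. False calls numbered 0 to 10, but other splits of the arrays called up to 1426 genes. Tables were read with the data.table package, version 1.17.8, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.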

Results

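Gene expression was measured in whole blood of 24 male 129S/J mice 24 h after X-ray or sham exposure, in wild-type mice and in mice lacking Parp1, a nuclear enzyme that makes poly(ADP-ribose) at DNA breaks. There were 5 wild-type arrays at 0 Gy, 5 at 6 Gy and 4 at 8.8 Gy, and 5 knockout arrays at 0 Gy and 5 at 6 Gy, each from 1 mouse. Per the labels, 8.8 Gy in wild-type and 6 Gy in knockout mice kill 50% within 30 days. The share of probes well above background was 48.8% ± 6.49 (SD) in wild-type 0 Gy, 49.4% ± 5.46 at 6 Gy and 48.8% ± 6.36 at 8.8 Gy, 39.1% ± 2.36 in knockout 0 Gy and 47.3% ± 3.89 in knockout 6 Gy arrays. All knockout 0 Gy arrays lay below the other groups of 5 (exact permutation p = 0.00794, adjusted p = 0.0794).

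The arrays lay on 10 slides scanned on 4 days, and these did not cross the groups. All wild-type 0 Gy arrays were scanned on day 4, all wild-type 6 Gy and 8.8 Gy arrays on day 3, and the knockout 0 Gy arrays on days 1 and 2. Arrays labelled knockout 6 Gy fell on day 1 (replicate 5), day 3 (replicates 1 to 3) and day 4 (replicate 4). Wild-type 0 Gy arrays thus shared no slide or day with wild-type irradiated or knockout 0 Gy arrays, and a fixed block links them only through knockout 6 Gy arrays.

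Parp1 was measured by 1 probe (NM_007415, mm9 chromosome 1, 182530341 to 182530639). The labels do not say which part of the gene the null allele lacks, so the probe checks the genotype only as far as that part stops this transcript. Relative to each array's 75th percentile, log2 Parp1 was -0.35, -0.49, -0.58, -0.94 and -0.71 in wild-type 0 Gy replicates 1 to 5, well above background on each. It was -1.27, -2.33, -1.88, -1.52 and -2.06 in wild-type 6 Gy replicates 1 to 5, with replicates 1 and 2 not well above background. Knockout 0 Gy replicates 1 to 5 gave -2.29, -2.81, -3.82, -2.90 and -3.16, none well above background. In arrays labelled knockout 6 Gy, replicates 2 to 5 gave -3.45, -5.01, -3.82 and -4.67, none well above background, whereas the array labelled knockout 6 Gy replicate 1 gave -1.67, well above background. In arrays labelled wild-type 8.8 Gy, replicates 1 to 3 gave -1.25, -1.56 and -1.59, and the array labelled wild-type 8.8 Gy replicate 4 gave -3.95, not well above background. Siglecf, an eosinophil surface lectin chosen here after the values were seen because it differed between the sham genotypes, was 0.59 on the array labelled knockout 6 Gy replicate 1 and -2.70, -2.28, -2.13 and -1.09 on replicates 2 to 5. On the array labelled wild-type 8.8 Gy replicate 4 it was 0.79, within the range of the wild-type arrays (-1.13 to 2.40). The Parp1 spot of that array lay in a dim patch in which bright spots fell by 1.98 (local median, log2).

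**Figure D1:**
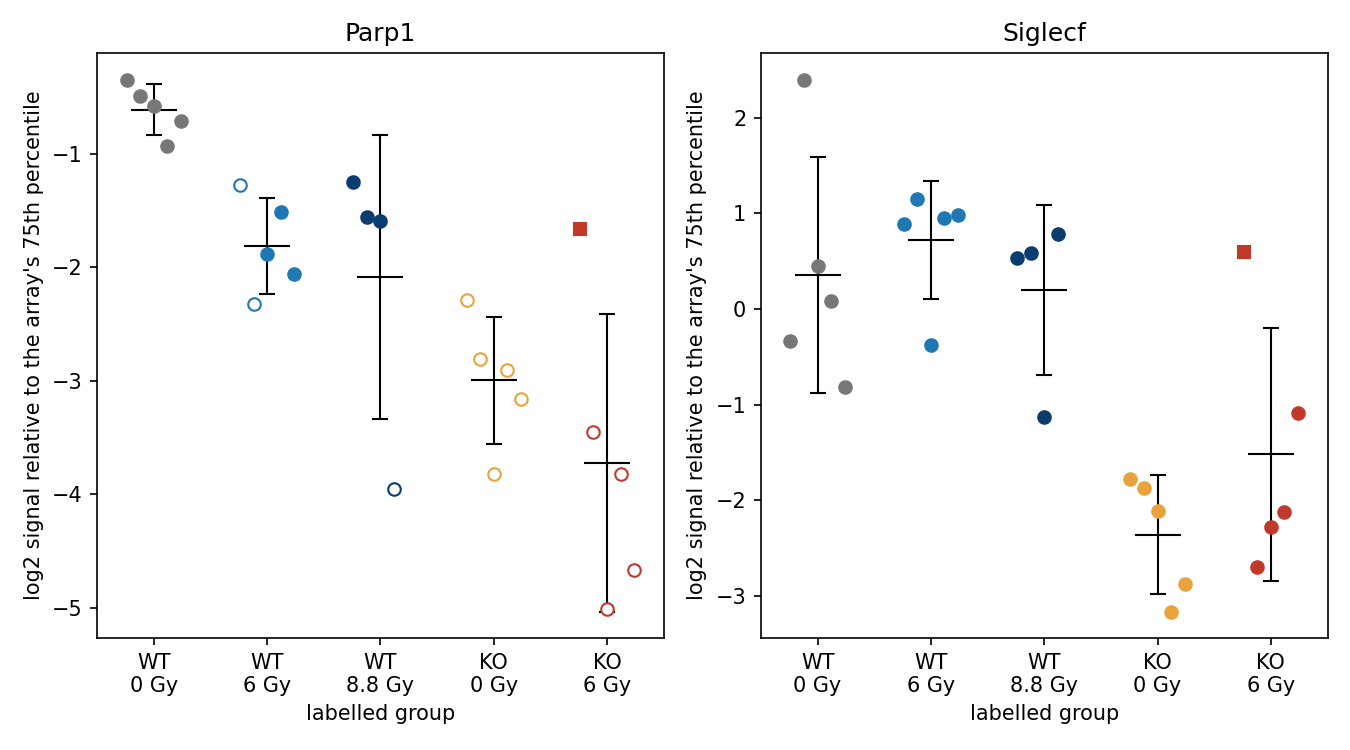
Log2 level of Parp1 and of Siglecf relative to each array's 75th percentile (vertical axes) in the 5 groups (horizontal axis), with 1 point per array (open where Parp1 was not well above background, square for the array labelled knockout 6 Gy replicate 1) and bars for the mean and SD. That array sits at -1.67 for Parp1 and 0.59 for Siglecf, apart from the other 4 arrays of its group.

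The arrays labelled knockout 6 Gy replicate 1 and wild-type 8.8 Gy replicate 2 were nearly equal. The SD of their log2 difference over 10768 probes was 0.167, against 0.262 for the next closest pair and a median of 0.901 over all 276 pairs of arrays (0.735 within groups), and only 34 probes differed by more than 1 log2 unit. Where a gene had a further probe, the difference at 1 probe hardly followed that at the other, with a correlation across 1254 genes of 0.0658. In every other pair this correlation was at least 0.207, median 0.623. Both stayed in the fits, as the labels put them in different groups, and counts, calls of named genes and main list medians are given without the array labelled knockout 6 Gy replicate 1 as well.

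**Figure D2:**
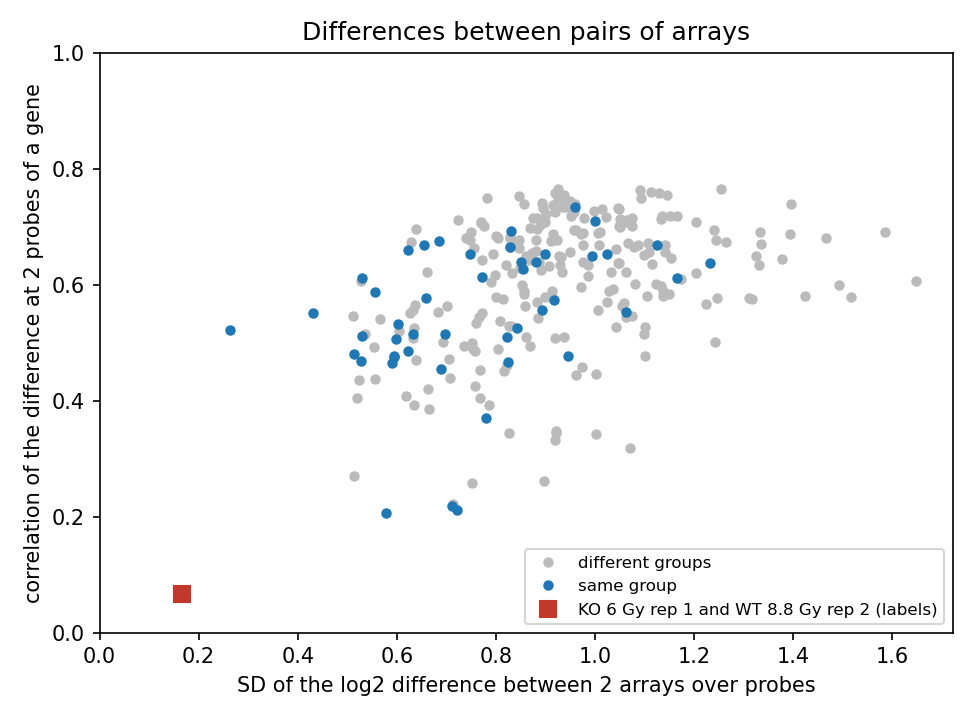
Each of the 276 pairs of arrays by the SD of their log2 difference (horizontal axis, log2 units) and the correlation across genes of the difference at 2 probes of a gene (vertical axis). The marked pair, the arrays labelled knockout 6 Gy replicate 1 and wild-type 8.8 Gy replicate 2, sits at 0.167 and 0.0658.

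Liver transcripts differed widely between arrays within every group. The mean log2 level of 23 hepatocyte markers was 2.52 ± 4.82 (SD) in wild-type 0 Gy, 1.24 ± 3.33 in wild-type 6 Gy, 4.05 ± 3.88 in wild-type 8.8 Gy, 0.469 ± 3.63 in knockout 0 Gy and 2.57 ± 4.21 in knockout 6 Gy arrays, with a smallest exact permutation p of 0.198 (adjusted p = 0.776). Within the wild-type 0 Gy group it ran from -2.90 to 7.06. Alb, which encodes serum albumin, ran from -4.53 to 9.20 over the 24 arrays. Heart muscle markers were at -2.84 ± 0.632 (SD) in wild-type 0 Gy, -1.38 ± 1.47 in wild-type 6 Gy, -1.13 ± 1.23 in wild-type 8.8 Gy, -2.82 ± 0.338 in knockout 0 Gy and -1.79 ± 2.64 in knockout 6 Gy arrays, highest on knockout 6 Gy replicate 3 (2.87). Their group means ranged over 1.71, against 1.51 within wild-type 0 Gy. Kupffer cell markers ranged over 4.35, lung markers over 2.67 and skeletal muscle markers over 2.23. The first principal component held 36.8% of the variance and had a correlation of -0.906 with the hepatocyte score over the 24 arrays. The level of the 9535 probes never well above background also moved with the groups, from -5.02 ± 0.698 in wild-type 0 Gy to -4.12 ± 0.301 in wild-type 6 Gy, -4.79 ± 0.942 in wild-type 8.8 Gy, -3.85 ± 0.303 in knockout 0 Gy and -4.71 ± 0.464 in knockout 6 Gy arrays (log2, SD).

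**Figure D3:**
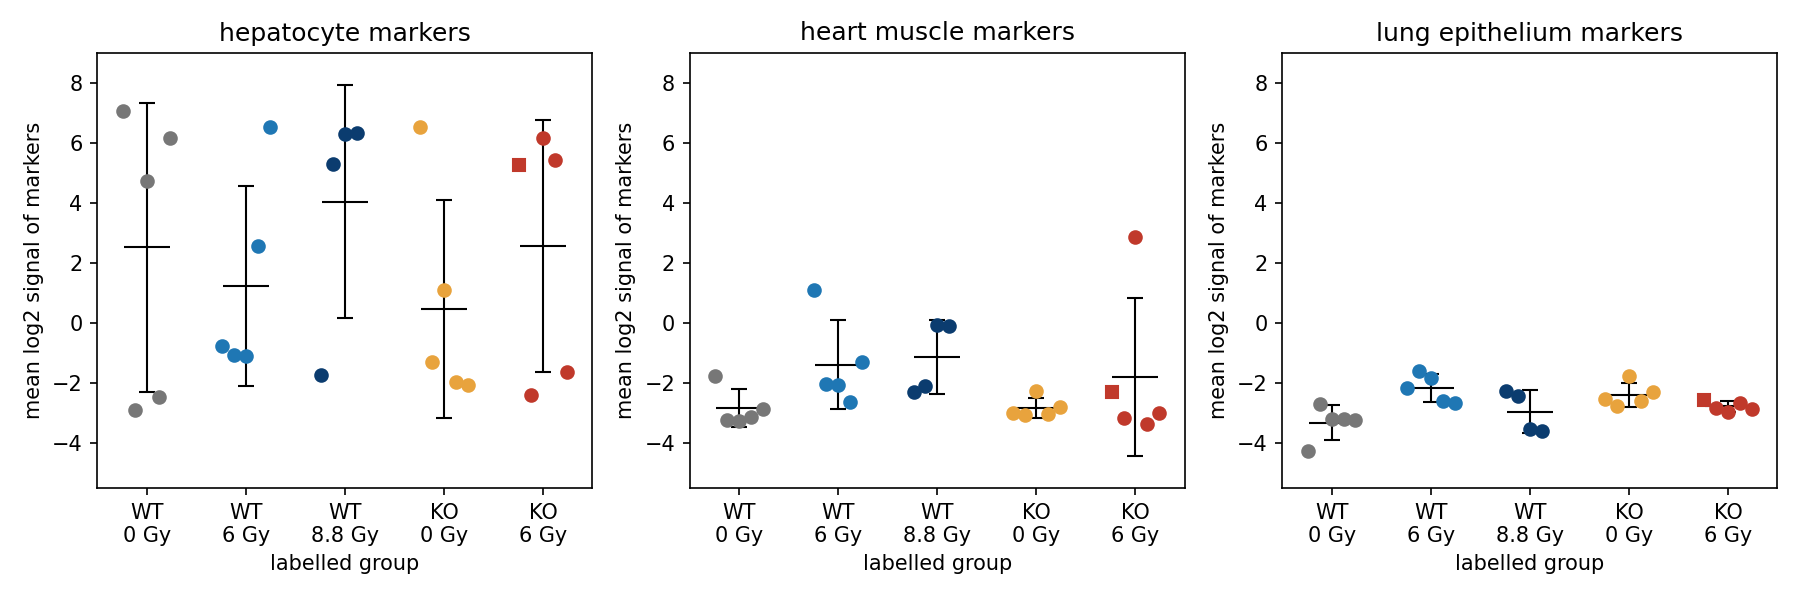
Mean log2 level of marker genes of other tissues relative to each array's 75th percentile (vertical axis) in the 5 groups (horizontal axis), with 1 point per array and bars for the mean and SD. Within the wild-type 0 Gy group alone the hepatocyte score runs from -2.90 to 7.06.

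The response of wild-type blood to 6 Gy was a rise of p53 targets and interferon-response genes together with a fall of lymphocyte and red-cell genes (n = 5 against 5 arrays). With an estimated correlation only the p53 list passed, and the others rest on the preset correlation and on single genes. Of 36 measured p53 targets, 20 rose and 1 fell, median log2 change 1.20, adjusted p = 1.89e-11, adjusted p = 0.00764 with an estimated correlation. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose by log2 4.16 ± 0.299 (SE), Plk2 by 2.93 ± 0.242, Bax, of apoptosis, by 1.93 ± 0.217, and Gtse1, a regulator of p53, was at least 5.48-fold higher (adjusted p from 1.96e-08 to 6.75e-06). Of 37 interferon-response genes, 24 rose and 1 fell, median 1.61 and adjusted p = 6.75e-14, though adjusted p = 0.173 with an estimated correlation. Oasl2, Oas2 and Oasl1, of the antiviral oligoadenylate synthetase family, rose by 5.06 ± 0.602, 4.51 ± 0.43 and 3.67 ± 0.33. Ifit3b rose by 4.43 ± 0.453, Rtp4 by 3.71 ± 0.336, and the antiviral GTPase gene Mx1 was at least 9.89-fold higher (adjusted p of the 6 genes from 3.63e-07 to 1.24e-05).

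In the lymphocyte lists of the 6 Gy response, 15 of 24 B cell markers fell and 1 rose, median -1.67 and adjusted p = 5.72e-08, adjusted p = 0.178 with an estimated correlation. Vpreb3, a gene of developing B cells, fell by 4.19 ± 0.386 (SE, log2) and Fcmr, the Fc receptor for IgM, fell by 3.40 ± 0.467. Of 28 T cell markers 20 fell and 0 rose, median -1.19, adjusted p = 4.89e-10, adjusted p = 0.439 with an estimated correlation. The T cell surface genes Thy1 and Cd5 changed by -2.35 ± 0.314 and -1.89 ± 0.325. Gpr174 was at least 3.18-fold lower. Of 10 MHC class II genes 6 fell, median -1.12, adjusted p = 0.00161, adjusted p = 0.439 with an estimated correlation, among them H2-Ob (-2.14 ± 0.245) and H2-Oa (-1.87 ± 0.363). With slide or scan day as a fixed block the class II median was -0.22 (adjusted p = 0.248) or -0.02 (adjusted p = 0.438). Of 29 antigen receptor signalling genes 8 fell, median -0.29, adjusted p = 0.0037, adjusted p = 0.758 with an estimated correlation. Lck, the T cell receptor kinase, fell by 1.86 ± 0.363. These genes had adjusted p between 4.23e-07 and 0.00155.

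Red-cell and proliferation genes were lower in wild-type blood at 6 Gy. Of 34 erythroid markers 19 fell and 2 rose, median -1.36, adjusted p = 1.79e-08, adjusted p = 0.489 with an estimated correlation. Ank1, of the red-cell membrane, was at least 5.47-fold lower. Of 28 cell cycle genes 12 fell and 1 rose, median -0.71, adjusted p = 0.000395, adjusted p = 0.439 with an estimated correlation, among them the mitotic genes Nusap1 (-3.37 ± 0.414, SE, log2) and Ube2c (-2.49 ± 0.422). Of 25 heat shock and redox genes 11 fell and 0 rose, median -0.68, adjusted p = 0.000195, adjusted p = 0.173 with an estimated correlation. The chaperone genes Hsph1 and Hsp90ab1 changed by -2.25 ± 0.31 and -1.44 ± 0.22. Fcer1a, the IgE receptor of basophils, gave -2.53 ± 0.405 and Mcpt8, a basophil protease, was at least 3.38-fold lower, while the 16 eosinophil and basophil markers had a median of 0.19 (adjusted p = 0.692). Ccdc151 changed by -4.12 ± 0.958 (adjusted p = 0.00476), a direction that turned to 0.61 with slide as a fixed block. For the other genes adjusted p lay between 1.65e-05 and 0.000479.

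Neutrophil and phagocytosis lists moved up in the 6 Gy response, and monocyte markers did not. Of 31 neutrophil markers 13 rose and 0 fell, median 0.79, adjusted p = 0.000781, adjusted p = 0.489 with an estimated correlation. Ly6g, a neutrophil surface protein, rose by 1.35 ± 0.267 (SE, log2) and Ceacam10 by 1.37 ± 0.3. Of 26 phagocytosis and Fc receptor genes 12 rose and 2 fell, median 1.09, adjusted p = 0.000753, adjusted p = 0.439 with an estimated correlation. The macrophage lectin Siglec1 was at least 2.93-fold higher and the IgG receptor Fcgr4 rose by 1.64 ± 0.306. Kupffer cell markers went from -1.13 ± 1.09 (SD) in sham to 0.235 ± 0.836 in 6 Gy arrays. The monocyte transcription factor gene Irf8 fell by 1.96 ± 0.314, while the 25 monocyte markers had a median of 0.23 (adjusted p = 0.836, 0 rose and 2 fell). Platelet markers had a median of 0.56 over 28 genes (adjusted p = 0.0131, adjusted p = 0.856 with an estimated correlation), which turned to -0.22 under median centring. Only Tmem40, a platelet marker, passed among them (1.05 ± 0.357, adjusted p = 0.0347), and it did not pass in 7 of the refits without 1 array (adjusted p up to 0.108). The platelet list lost its call in 3 refits (adjusted p up to 0.14). The adjusted p of the other named genes lay between 7.76e-05 and 0.00324.

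Ribosomal protein genes had a median of -0.40 at 6 Gy (39 genes, 5 fell and 1 rose, adjusted p = 0.000157, adjusted p = 0.655 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.54 (40 genes, 7 fell, adjusted p = 0.000462, adjusted p = 0.758 with an estimated correlation). Of 22 double-strand break repair genes 5 rose and 3 fell, median 0.03 (adjusted p = 0.874). Xrcc6, the Ku70 subunit of end joining, fell by 0.78 ± 0.153 (SE, log2, adjusted p = 0.00159) and Bard1, the partner of Brca1, rose by 1.53 ± 0.383 (adjusted p = 0.00733). Ccl3, a chemokine, was at least 2.42-fold lower (adjusted p = 0.000493), while the 23 NF-kappaB genes went both ways (5 rose, 5 fell, median 0.07, adjusted p = 0.755). The other lists did not pass, among them base excision repair (-0.03, adjusted p = 0.569), the PARP family (0.01, 0.699) and NAD metabolism (-0.15, 0.874). Parp1 itself differed by log2 -1.20 ± 0.508 and did not pass (adjusted p = 0.082).

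In all, 3433 of 13023 genes passed limma's threshold at 6 Gy in wild type, 2020 higher and 1413 lower, and 5177 had an unadjusted p under 0.05. Of the 25 named genes picked by adjusted p, which favours this, 24 lay beyond the sham mean in every irradiated array, all but Tmem40. The calls split 533 higher and 5561 lower under median centring, which moved the median of all genes by -0.78, 634 and 818 after normexp, and 730 and 983 over probes detected on all arrays. Of the higher calls 63.7% were on probes not detected on every array, against 41.8% of all genes tested (Fisher's exact test, 4.13e-103), and the level of never-detected probes moved by 0.899 between these groups. With slide as a fixed block limma called 0 genes (1423 at unadjusted p under 0.05), and with scan day 12, while all 37 named genes that passed kept their sign with scan day and 36 with slide. With slide or day fixed, list medians were 0.91 or 0.97 for p53 targets and 1.90 or 2.43 for interferon. They were -2.04 or -2.02 for B cells, -1.16 or -1.32 for T cells, and -0.95 or -1.40 for erythroid markers. Both fits rest on knockout 6 Gy replicate 4. Without wild-type 6 Gy replicate 3 the count was 2258.

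At 8.8 Gy, the dose lethal to 50% of wild-type mice, wild-type blood had higher p53-target, interferon-response and platelet RNA and lower B cell, T cell and ribosomal protein RNA than sham blood (n = 4 against 5 arrays, among them the array labelled wild-type 8.8 Gy replicate 4). Only the p53 and B cell lists passed with an estimated correlation. Of 36 p53 targets 21 rose and 0 fell, median 1.37, adjusted p = 8.86e-19, adjusted p = 0.000394 with an estimated correlation. Gtse1 was at least 8.13-fold higher, and Plk2, Bax and Apaf1, the scaffold of the apoptosome, rose by 3.19 ± 0.257, 1.37 ± 0.23 and 1.69 ± 0.321 (SE, log2). Of 37 interferon-response genes 23 rose and 0 fell, median 1.37, adjusted p = 1.35e-16, adjusted p = 0.112 with an estimated correlation. Oasl2 rose by 5.24 ± 0.638, Ifit3b by 4.99 ± 0.48, Oas2 by 4.49 ± 0.456, Oasl1 by 4.13 ± 0.35 and Slfn4 by 4.57 ± 0.574. Tmem35a was at least 10.4-fold higher. For these genes adjusted p lay between 6.18e-08 and 0.00154.

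Of 24 B cell markers 19 fell and 0 rose at 8.8 Gy, median -2.31, adjusted p = 2.91e-15, adjusted p = 0.0393 with an estimated correlation. Vpreb3 fell by 4.31 ± 0.409 (SE, log2), Cd72, a B cell co-receptor, fell by 3.48 ± 0.451, and Blnk fell by 3.60 ± 0.652. Of 28 T cell markers 21 fell and 0 rose, median -1.56, adjusted p = 3.85e-18, adjusted p = 0.136 with an estimated correlation. Thy1 fell by 3.78 ± 0.333, Cd3g, a T cell receptor chain, fell by 2.59 ± 0.309, Lck fell by 2.63 ± 0.385, and Dapl1 had the largest fall, -5.58 ± 0.42. Gpr174 was at least 5.08-fold lower. Of 10 MHC class II genes 7 fell, median -1.56, adjusted p = 3.5e-07, adjusted p = 0.136 with an estimated correlation. H2-Ob fell by 2.79 ± 0.26. Of 39 ribosomal protein genes 27 fell and 0 rose, median -1.003, adjusted p = 1.61e-16, adjusted p = 0.136 with an estimated correlation. Rps27 changed by -1.31 ± 0.218. Fcer1a and Mcpt8 changed by -3.62 ± 0.429 and -3.05 ± 0.505. Adjusted p ran from 4.85e-08 to 0.000987 over these genes.

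Platelet markers rose at 8.8 Gy, 15 of 28 with 0 falling, median 1.31, adjusted p = 5.72e-12, adjusted p = 0.27 with an estimated correlation. Tubb1, the tubulin of platelets, rose by 1.85 ± 0.365 (SE, log2) and Thbs1 by 2.08 ± 0.44. Of 31 neutrophil markers 11 rose and 0 fell, median 0.81, adjusted p = 9.45e-06, adjusted p = 0.27 with an estimated correlation. Trem1 rose by 1.55 ± 0.286. Of 26 phagocytosis genes 9 rose and 1 fell, median 0.99, adjusted p = 4.02e-05, adjusted p = 0.188 with an estimated correlation. Lamp2, of the lysosome membrane, rose by 1.37 ± 0.21 and Siglec1 was at least 2.21-fold higher, with Kupffer cell markers at 0.109 ± 0.836 (SD) against -1.13 ± 1.09 in sham arrays. Of 34 erythroid markers 7 fell and 2 rose, median -0.79, adjusted p = 0.002, adjusted p = 0.692 with an estimated correlation. Epb4.2, a red-cell membrane protein, was at least 2.72-fold lower, with a turned sign after normexp (0.39), while Epor rose by 2.19 ± 0.374. The erythroid median was -0.21 with slide and -1.08 with scan day as a fixed block. The progenitor transcription factors Gfi1b and Meis1 rose by 1.91 ± 0.383 and 1.76 ± 0.394, and the 12 progenitor markers had a median of 0.92 (3 rose and 1 fell, adjusted p = 0.0493, adjusted p = 0.525 with an estimated correlation). That call was lost in 4 refits without 1 array (adjusted p up to 0.0748). These genes had adjusted p between 0.000218 and 0.00476.

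Among the other lists at 8.8 Gy, cell cycle genes had a median of -0.48 (7 of 28 fell, 1 rose, adjusted p = 0.0368, adjusted p = 0.601 with an estimated correlation), which was 0.01 after normexp. Mcm5 fell by 1.61 ± 0.296 (SE, log2). The cell cycle call was lost in 4 of the 9 refits without 1 array (adjusted p up to 0.104). Base excision repair had a median of -0.23 (2 of 20 fell, adjusted p = 0.0493, adjusted p = 0.367 with an estimated correlation), which turned to 0.12 in the authors' table and was lost in 7 of the 9 refits without 1 array (adjusted p up to 0.0975). Heat shock genes had a median of -0.33 (9 of 25 fell, adjusted p = 0.0234, adjusted p = 0.27 with an estimated correlation), lost without wild-type 8.8 Gy replicate 1 (adjusted p = 0.0644), and Hsph1 fell by 1.92 ± 0.329. Oxidative phosphorylation had a median of -0.50 (4 of 40 fell, adjusted p = 0.00202, adjusted p = 0.692 with an estimated correlation), lost in 2 refits (adjusted p up to 0.0772). Parp3 changed by -1.43 ± 0.294 (0.41 after normexp). Irf8 changed by -1.98 ± 0.333, Xrcc6 by -0.79 ± 0.162 and Ccl3 by -3.09 ± 0.478, the last with a turned sign after normexp (0.14). The other 12 lists, among them the PARP family and eosinophil and basophil markers, had adjusted p of at least 0.0859. Adjusted p of named genes ran from 0.000229 to 0.00283. Parp1 gave -1.48 ± 0.539 (adjusted p = 0.0641), lowered by 8.8 Gy replicate 4 (-3.95, dim patch).

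In all, 2089 genes passed limma's threshold at 8.8 Gy, 916 higher and 1173 lower, and 3976 had an unadjusted p under 0.05. All 26 named genes picked by adjusted p, which favours this, lay beyond the sham mean in all 4 irradiated arrays. The split was 499 higher and 1992 lower under median centring, which moved the median of all genes by -0.317, and 1150 and 802 in the authors' table, which moved it by 0.23. With slide as a fixed block limma called 0 genes (1114 at unadjusted p under 0.05), and with scan day 23, while all 38 kept their sign in both. With slide or day fixed, list medians were 1.11 or 0.97 for p53 targets and 2.20 or 1.90 for interferon. They were -2.51 or -2.64 for B, -1.36 or -1.79 for T cells, 1.86 or 1.25 for platelets, and -0.77 or -0.97 for ribosomal proteins. Both fits rest on knockout 6 Gy replicate 4. Without wild-type 8.8 Gy replicate 2 the count was 1257, and without the array labelled wild-type 8.8 Gy replicate 4 it was 1548.

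Knockout blood at 6 Gy, the dose lethal to 50% of knockout mice, had higher p53-target, interferon-response, platelet and phagocytosis RNA and lower B cell, T cell and red-cell RNA than knockout sham blood (n = 5 against 5 arrays). With an estimated correlation only the p53 list passed. Without the array labelled knockout 6 Gy replicate 1 all 47 named genes passed, and the medians of these lists were 1.70, 1.74, 1.20, 1.33, -2.37, -1.36 and -1.70 in this order (adjusted p up to 2.16e-06). Of 36 p53 targets 24 rose and 0 fell, median log2 change 1.68 (1.31 with bounded genes at their bound), adjusted p = 1.26e-19, adjusted p = 3e-04 with an estimated correlation. Cdkn1a was at least 12-fold and Plk2 at least 1.96-fold higher, and Bax rose by 1.97 ± 0.217 (SE, log2). Of 37 interferon-response genes 27 rose and 1 fell, median 1.65, adjusted p = 4.08e-15, adjusted p = 0.109 with an estimated correlation. Oas2 rose by 4.65 ± 0.43, Slfn4 by 4.43 ± 0.541 and Oasl1 by 3.99 ± 0.33, and Oasl2 was at least 5.89-fold and Tmem35a at least 4.73-fold higher. Saa3 rose most, by 5.32 ± 1.16. Of 29 apoptosis genes 13 rose and 2 fell, median 0.70, adjusted p = 0.000205, adjusted p = 0.0517 with an estimated correlation. Apaf1 was at least 1.51-fold higher. For these genes adjusted p lay between 1.93e-08 and 0.00219.

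In the lymphocyte lists of the knockout response, 18 of 24 B cell markers fell and 1 rose, median -2.39, adjusted p = 1.02e-12, adjusted p = 0.0517 with an estimated correlation. Vpreb3 fell by 4.39 ± 0.386 (SE, log2). Of 28 T cell markers 21 fell and 0 rose, median -1.39, adjusted p = 7.89e-14, adjusted p = 0.252 with an estimated correlation. Thy1 changed by -3.24 ± 0.314, Cd8a by -2.93 ± 0.411, Lck by -1.87 ± 0.363 and Dapl1 by -4.42 ± 0.396. Of 10 MHC class II genes 4 fell, median -0.92, adjusted p = 0.000736, adjusted p = 0.321 with an estimated correlation, among them H2-Ob (-2.14 ± 0.245) and H2-Oa (-1.96 ± 0.363). Of 34 erythroid markers 24 fell and 2 rose, median -1.61, adjusted p = 1.24e-09, adjusted p = 0.349 with an estimated correlation. Epb4.2 was at least 5.95-fold lower. Of 39 ribosomal protein genes 22 fell and 0 rose, median -0.64, adjusted p = 3.92e-09, adjusted p = 0.321 with an estimated correlation, among them Rpl8 (-0.94 ± 0.2). Adjusted p ran from 3.44e-07 to 0.0018 over these genes.

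Of 28 platelet markers 14 rose and 0 fell in knockout blood, median 1.11, adjusted p = 1.23e-08, adjusted p = 0.349 with an estimated correlation. Tmem40 rose by 1.79 ± 0.357 (SE, log2) and Tubb1 by 1.61 ± 0.344. Of 26 phagocytosis genes 14 rose and 1 fell, median 1.35, adjusted p = 1.86e-06, adjusted p = 0.138 with an estimated correlation, and with slide as a fixed block their median was 0.67 (adjusted p = 0.0682). Lamp2 rose by 1.68 ± 0.198 and Clec7a by 1.62 ± 0.267. Kupffer cell markers went from -1.62 ± 0.869 (SD) in sham arrays to 0.234 ± 1.12 in arrays labelled knockout 6 Gy. Of 31 neutrophil markers 11 rose and 2 fell, median 0.89, adjusted p = 0.000179, adjusted p = 0.349 with an estimated correlation. Trem1 rose by 1.51 ± 0.27 and Slpi by 1.58 ± 0.312. Meis1 and Gfi1b rose by 2.55 ± 0.371 and 2.09 ± 0.361. Fcer1a was at least 4.95-fold and Mcpt8 at least 3.62-fold lower. These genes had adjusted p between 7.44e-06 and 0.00193.

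Among repair and metabolism genes of the knockout response, Parp3 fell by 1.44 ± 0.277 (SE, log2) and Adprh, which removes ADP-ribose from arginine, rose by 0.82 ± 0.209. The NAD-dependent deacylase genes Sirt3 and Sirt5 rose by 1.40 ± 0.262 and 1.69 ± 0.297. Rad51d, of homologous recombination, was at least 1.23-fold higher, with a turned sign after normexp (-0.02), and Xrcc6 fell by 0.81 ± 0.153. Cell cycle genes had a median of -0.50 (9 of 28 fell and 2 rose, adjusted p = 0.0111, adjusted p = 0.49 with an estimated correlation), and Nusap1 fell by 2.79 ± 0.414. Heat shock genes had a median of -0.52 (10 of 25 fell and 0 rose, adjusted p = 0.0136, adjusted p = 0.318 with an estimated correlation), which was 0.04 after normexp and lost its call in 2 refits without 1 array (adjusted p up to 0.127). Hsph1 fell by 2.25 ± 0.31. Oxidative phosphorylation had a median of -0.34 (7 of 40 fell, adjusted p = 0.028, adjusted p = 0.765 with an estimated correlation), which turned to 0.17 after normexp. It lost its call in 5 of the 10 refits without 1 array, 1 of them the array labelled knockout 6 Gy replicate 1 (adjusted p up to 0.4). Cox7a2 fell by 1.88 ± 0.318. The other 13 lists, among them PARP family, repair, NAD, progenitor and basophil genes, had adjusted p of at least 0.0803. Over the genes named here adjusted p ran from 3.86e-05 to 0.00708. Parp1 was well above background on no sham array, so no change is given.

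In all, 2970 genes passed limma's threshold in the knockout response, 1608 higher and 1362 lower, and 4665 had an unadjusted p under 0.05. Without the array labelled knockout 6 Gy replicate 1 the count was 2596. All 35 named genes picked by adjusted p, which favours this, lay beyond the sham mean in all 5 irradiated arrays. The authors' table gave 1593 higher and 774 lower. The level of never-detected probes moved by -0.86 between these groups. With slide or scan day as a fixed block, 53 and 56 genes passed, and all 47 named genes kept their sign. Within scan day 1 (slide 9, the only batch with both groups, 1 against 2 arrays) the list medians were 1.88 for p53 targets, 1.35 for interferon, -1.55 for B cells, -0.68 for T cells, 1.77 for platelets, -0.98 for erythroid markers and 0.67 for phagocytosis.

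**Figure D4:**
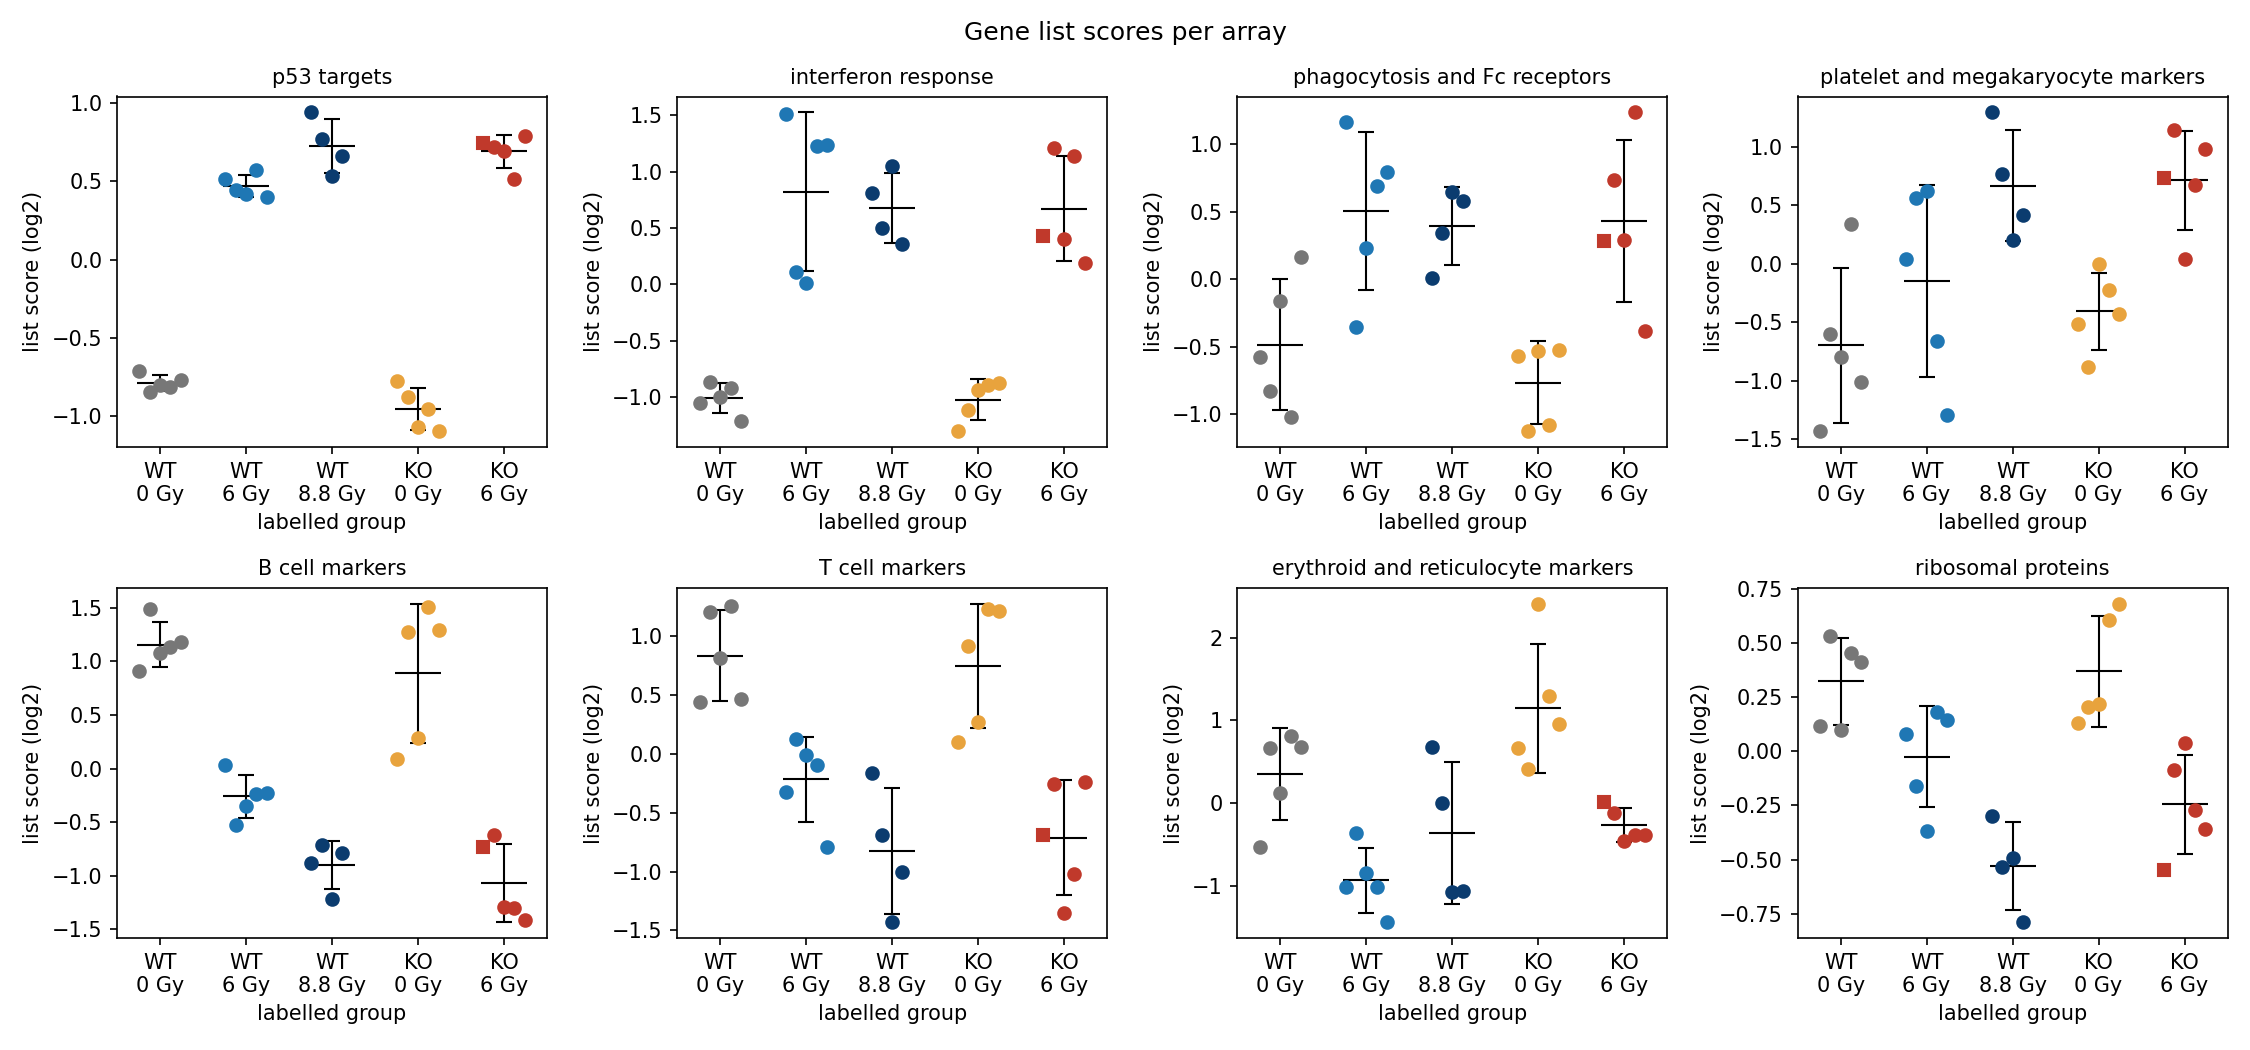
Mean-centred log2 score per array (vertical axes) of 8 gene lists in the 5 groups (horizontal axis), with 1 point per array, bars for the mean and SD and a square for the array labelled knockout 6 Gy replicate 1. The p53 and interferon scores are higher and the B and T cell scores lower in all irradiated groups than in the sham groups, by a median of 1.20, 1.37 and 1.68 for p53 targets.

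The 3 responses shared many calls. Of the genes tested, 1088 passed in both wild-type responses (420 higher, 668 lower, 0 opposite), where independent lists would share 142 and 127. Both use the same sham arrays. Unchanged groups simulated against them had a median correlation of log2 changes across genes of 0.506 (-0.649 to 0.96). The observed correlation was 0.729 (Spearman 0.748) with a covariance of 0.532 against 0.0982 ± 0.124 (SD) simulated, a difference of 0.434. With the sham arrays split between the responses, 20 splits shared a median of 228.5 genes (139 to 381), with 24 and 16.7 expected. The median correlation was 0.571 (0.121 to 0.738). Neither check removes scan day (3 in both irradiated groups, 4 in sham). The knockout response shared 1375 calls with the 8.8 Gy response (765 higher and 610 lower, 0 opposite, against 113 and 123 for independent lists), with a correlation of 0.594 (Spearman 0.476). It shared 1170 with the wild-type 6 Gy response (463 higher, 707 lower and 41 opposite, against 249 and 148), with a correlation of 0.309 (Spearman 0.238). Without the array labelled knockout 6 Gy replicate 1 these were 1157 (0.528) and 1028 (0.263). Across all 3 responses, 761 of the 5579 genes called in any were called in the same direction in each, 324 higher and 437 lower. Genes are not independent replicates in these correlations.

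In sham mice, knockout blood had lower Siglecf than wild-type blood (n = 5 against 5 arrays). Parp1 was at least 2.59-fold lower (adjusted p = 0.0312), and Siglecf fell by 2.72 ± 0.586 (SE, log2, adjusted p = 0.0319), the only one of 16 eosinophil and basophil markers to pass (median -0.30, adjusted p = 0.129). Prpf19 was at least 1.48-fold lower and Atpaf2 fell by 0.93 ± 0.184 (adjusted p = 0.0289 and 0.0271). The largest rises were Ccdc30 (3.09 ± 0.692), A4galt (2.83 ± 0.517), Mok (2.78 ± 0.643), Mroh2a (2.36 ± 0.447), Dppa2 (2.34 ± 0.511) and Dock4 (2.33 ± 0.378), with adjusted p from 0.0191 to 0.0464. Erythroid markers had a median of 0.76 over 34 genes (adjusted p = 3.05e-07, adjusted p = 0.808 with an estimated correlation) with no member past the threshold in limma. Xpo7 and Urod, the members with the smallest p, gave 1.35 ± 0.396 (adjusted p = 0.0873) and 1.22 ± 0.409 (adjusted p = 0.12). Neutrophil markers had a median of 0.45, MHC class I genes -0.34 and apoptosis genes -0.29 (adjusted p = 0.0362 each, adjusted p = 0.808 with an estimated correlation). These lists lost their calls in 4, 3 and 2 of the 10 refits without 1 array (adjusted p up to 0.194, 0.194 and 0.0604). The erythroid, neutrophil, MHC class I and apoptosis medians were 1.03, -0.08, 0.02 and -0.23 with slide as a fixed block (adjusted p = 2.94e-07, 0.699, 0.923 and 0.189). With scan day as a fixed block they were 0.26, -0.37, -0.21 and -0.29 (adjusted p = 0.0998, 0.84, 0.84 and 0.744).

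In all, 88 genes passed limma's threshold between the sham genotypes, 82 higher and 6 lower in knockout blood, and 2681 had an unadjusted p under 0.05, where 651.2 would be expected by chance, so the count does not show that few genes differ. All 10 named genes were picked for values that did not overlap between the groups. The count was 1 without wild-type 0 Gy replicate 1 or 3 or knockout 0 Gy replicate 3, and 353 without knockout 0 Gy replicate 1. Each of the 10 named genes lost its call in at least 1 of the 10 refits, Parp1 in 7 and Siglecf in 6, with the highest adjusted p from 0.0926 (Dock4) to 0.172 (Ccdc30 and Mok). The split was 44 higher and 11 lower under quantile normalisation, and median centring moved the median of all genes by -0.182. No slide or scan day held both groups. With slide as a fixed block limma called 0 genes (295 at unadjusted p under 0.05), with scan day 1, and with slide as a random block 0 (1661). The level of never-detected probes was 1.16 higher in knockout arrays, and with the hepatocyte score as a covariate 191 genes passed.

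At equal dose, platelet and erythroid lists were higher and the B cell list lower in knockout than in wild-type blood at 6 Gy with the preset correlation alone (n = 5 against 5 arrays, 1 of them the array labelled knockout 6 Gy replicate 1). Of 28 platelet markers 1 passed over all genes and 15 adjusted over the list alone, all higher, median 0.93, adjusted p = 1.58e-09, adjusted p = 0.748 with an estimated correlation. Itga2b, the platelet integrin, rose by 2.15 ± 0.497 (SE, log2, adjusted p = 0.0447) and Gp5 gave 1.45 ± 0.383 (adjusted p = 0.0583). Of 34 erythroid markers 1 passed, and 4 adjusted over the list alone, all higher, median 0.69, adjusted p = 1.12e-05, adjusted p = 0.748 with an estimated correlation. That gene, Ank1, was at least 2.39-fold higher (adjusted p = 0.0367). No B cell marker passed over all genes in limma, while 11 were lower and 1 higher adjusted over the list alone, median -1.02, adjusted p = 4.28e-05, adjusted p = 0.748 with an estimated correlation. Cd79a, of the B cell receptor, gave -1.19 ± 0.297 (adjusted p = 0.0517) and Pou2af1 -1.41 ± 0.379 (adjusted p = 0.0599). T cell markers had a median of -0.41 (3 lower adjusted over the list alone, adjusted p = 0.00263, adjusted p = 0.748 with an estimated correlation), with Thy1 at -1.20 ± 0.314 (adjusted p = 0.0559) and Cd8a at -1.36 ± 0.411 (adjusted p = 0.0722). That direction turned to 0.23 under median centring.

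The other lists past the preset test at 6 Gy were neutrophil markers (median 0.34, adjusted p = 0.00572), ribosomal proteins (-0.24, 0.0203), MHC class II (-0.57, 0.0231), p53 targets (0.23, 0.033), NK cells (-0.40, 0.033), and cell cycle (0.16), oxidative phosphorylation (0.17) and heat shock (0.31) genes at 0.049 each. None kept its call with an estimated correlation (adjusted p = 0.748, adjusted p = 0.761 for oxidative phosphorylation). Under median centring NK cells turned to 0.24, MHC class II to 0.07 and ribosomal proteins to 0.40, and under quantile normalisation oxidative phosphorylation turned to -0.01. Of the genes past the threshold, Ube2h rose by 1.96 ± 0.403 (SE, log2), Ell2 by 1.91 ± 0.407, and Casd1 by 1.77 ± 0.315. Aff4 was at least 1.96-fold and Pigg at least 1.33-fold higher, and Lamp2 rose by 0.97 ± 0.198. Hoxc10 was at least 2.22-fold, Kcng1 at least 2.09-fold, Kremen2 at least 2.46-fold and Bpifb9b at least 2.36-fold lower. Rsph6a changed by -2.47 ± 0.514, Nol3 by -2.28 ± 0.524 and Parp3 by -1.18 ± 0.277. For these genes adjusted p lay between 0.0172 and 0.0473. Siglecf gave -2.24 ± 0.586 (adjusted p = 0.0559) and Parp1 -1.91 ± 0.508 (adjusted p = 0.0583), both with the array labelled knockout 6 Gy replicate 1 included.

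In all, 114 genes passed limma's threshold at 6 Gy between the genotypes, 49 higher and 65 lower in knockout blood, and 3035 had an unadjusted p under 0.05. Of the 15 named genes 12 were picked for values without overlap. Without the array labelled knockout 6 Gy replicate 1 all 15 passed, with 534 in all (105 higher, 429 lower). Parp1 and Siglecf (-2.77) passed too (adjusted p = 0.0203), which leaving out an array high in both favours. Without it the platelet, erythroid, B cell and T cell medians were 0.94, 0.65, -1.07 and -0.39 (adjusted p up to 0.00699), and p53 targets, ribosomal proteins, cell cycle and heat shock genes lost their calls (adjusted p from 0.0677 to 0.18). Leaving out wild-type 6 Gy replicate 1, 2, 3 or 4 gave 1, 0 (2566 at unadjusted p under 0.05 in limma), 37 and 261 genes. Each named gene lost its call in at least 1 refit without 1 array, with the highest adjusted p from 0.0562 (Casd1 and Pigg) to 0.108 (Nol3). The share of higher calls was 43% and moved with the scaling, from 120 higher and 845 lower with the percentile of probes detected on all arrays to 3639 and 168 under median centring, with 190 and 133 under quantile normalisation, 16 and 2 after normexp, 345 and 81 in the authors' table and 21 and 5 over probes detected on all arrays. The median of all genes moved by 0.638 (median centring), -0.151 (percentile of detected probes) and 0.116 (authors' table). Of the lower calls 83.1% were on probes not detected on every array (Fisher's exact test, 9.22e-12), and the level of never-detected probes moved by -0.595.

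With slide or scan day as a fixed block, 28 genes and 1 gene passed between the genotypes at 6 Gy, and with the hepatocyte score as a covariate 1397. The platelet, erythroid, B cell and T cell medians were 1.07, 1.06, -0.54 and -0.30 with slide (adjusted p = 5.39e-10, 1.23e-10, 0.0145 and 0.0845) and 0.89, 0.70, -0.62 and -0.49 with scan day (adjusted p = 7.14e-08, 3.16e-07, 0.00161 and 0.00161). Within slide 4 (1 knockout against 2 wild-type arrays) they were 2.24, 1.07, -0.47 and 0.18. Within slide 2, where the knockout array is the array labelled knockout 6 Gy replicate 1 (1 against 1), they were 0.10, 0.42, -0.30 and -0.77.

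Whether 8.8 Gy and 6 Gy differed in wild-type blood stayed open (n = 4 against 5, with the array labelled 8.8 Gy replicate 4). No gene passed, and lists passed with the preset but not an estimated correlation. Ribosomal proteins had a median log2 difference of -0.54 (18 of 39 lower adjusted over the list alone), adjusted p = 5.78e-10, adjusted p = 0.702 with an estimated correlation, with Rpl34 at -0.89 ± 0.203 (SE) and Rps23 at -0.95 ± 0.225 (adjusted p = 0.0958 each). Platelet markers had a median of 0.86 (12 of 28 higher adjusted over the list alone), adjusted p = 3.55e-09, adjusted p = 0.702 with an estimated correlation, with Tubb1 at 1.24 ± 0.365 (adjusted p = 0.129) and Itga2b at 1.73 ± 0.527 (adjusted p = 0.139). This direction turned to -0.14 after normexp. Erythroid markers had a median of 0.52 (5 of 34 higher adjusted over the list alone), adjusted p = 9.99e-06, adjusted p = 0.731 with an estimated correlation, with Ank1 at least 1.82-fold higher (adjusted p = 0.104). T cell markers had a median of -0.64 (7 of 28 lower adjusted over the list alone), adjusted p = 7.16e-05, adjusted p = 0.731 with an estimated correlation, with Thy1 at -1.43 ± 0.333 (adjusted p = 0.0958) and Cd3g at -1.17 ± 0.309 (adjusted p = 0.113). B cell markers had a median of -0.65 (2 lower adjusted over the list alone), adjusted p = 0.000869, adjusted p = 0.702 with an estimated correlation, and turned to 0.12 after normexp. Parp3 gave -1.45 ± 0.294 (adjusted p = 0.0844). Parp1 gave -0.28 ± 0.539 (adjusted p = 0.812), lowered by 8.8 Gy replicate 4 (-3.95, dim patch).

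Smaller shifts between the wild-type doses were -0.65 for NK cells (adjusted p = 0.00576), -0.61 for MHC class II (0.0093), 0.22 for p53 targets (0.0172), 0.33 for heat shock (0.0247) and 0.15 for cell cycle genes (0.0281), none kept with an estimated correlation (adjusted p = 0.731 for NK cells, MHC class II and cell cycle, adjusted p = 0.702 for the others). After normexp p53 targets turned to -0.27 and heat shock genes to -0.53, and the p53 call was lost without wild-type 8.8 Gy replicate 1 (adjusted p = 0.077). By limma 0 genes passed, with 18% of genes at unadjusted p under 0.05 and a smallest adjusted p of 0.0844. An ordinary linear model also gave 0 (2327 at unadjusted p under 0.05), array weights 1134, quantile normalisation 136 and the hepatocyte score as a covariate 592. Leaving out wild-type 8.8 Gy replicate 1 gave 1 gene and replicate 3 gave 6. All these arrays were scanned on day 3. With slide as a fixed block 10 genes passed, and the ribosomal, platelet, erythroid, T cell and B cell medians were -0.53, 0.88, 0.88, -0.23 and -0.44 (adjusted p = 5.57e-09, 1.34e-07, 4.06e-10, 0.149 and 0.009). Within slide 1 (1 against 1 array) they were -0.61, 1.19, 1.76, 0.24 and -0.77, and within slide 3 (1 against 1) -0.16, 0.17, 0.70, -0.68 and -0.29. The never-detected probes moved by -0.673.

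At equal lethality, no gene told knockout blood at 6 Gy from wild-type blood at 8.8 Gy, and only the ribosomal and neutrophil lists passed, with the preset correlation alone (n = 5 against 4 arrays). This does not show that the groups are equal, as 22% of simulated changes of 1 log2 were found in this comparison. The arrays labelled knockout 6 Gy replicate 1 (nearly equal to wild-type 8.8 Gy replicate 2) and wild-type 8.8 Gy replicate 4 are included. Both narrow the Parp1 gap (-1.67, -3.95). Ribosomal proteins had a median of 0.30 (adjusted p = 2.48e-10, adjusted p = 0.996 with an estimated correlation), with Rps24 at 0.66 ± 0.252 (SE, log2) and Rps20 at 0.85 ± 0.388. Neutrophil markers had a median of 0.20 (adjusted p = 0.0142, adjusted p = 0.996 with an estimated correlation), with Retnlg at 0.95 ± 0.431. The neutrophil call was lost in 2 of the refits without 1 array (adjusted p up to 0.178). The p53 targets had a median of 0.00 and the interferon genes -0.04, and no other list had an adjusted p under 0.179. Siglecf gave -1.72 ± 0.621, the erythroid Hemgn -1.25 ± 0.36 and Parp1 -1.63 ± 0.539, each with adjusted p = 0.999. By limma 0 genes passed, with 269 at unadjusted p under 0.05, where 651.2 would be expected by chance, and an ordinary linear model gave 0 as well (279). Without the array labelled knockout 6 Gy replicate 1 the count was again 0 in limma (597 at unadjusted p under 0.05), and ribosomal (0.39, adjusted p = 3.36e-11), neutrophil (0.23, 0.0347) and oxidative phosphorylation genes (0.21, 0.0347) passed the preset test. Normexp alone gave 5747 genes, and after it the SD of the values within an array was 1.15 ± 0.266 over the wild-type 8.8 Gy arrays against 1.79 ± 0.0796 over the knockout 6 Gy arrays. With slide as a fixed block the ribosomal and neutrophil medians were 0.36 and 0.35 (adjusted p = 7.97e-08 and 0.00396), and with scan day 0.36 and 0.18 (adjusted p = 3.02e-12 and 0.081). Within slide 5 (1 against 2 arrays) they were 0.60 and 0.29.

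Whether the response to 6 Gy differed between the genotypes was tested as an interaction at equal dose. Most genes that passed had a lower response in knockout than in wild-type blood. The cell cycle, base excision and double-strand break repair lists did not pass (medians 0.28, -0.05 and 0.27, adjusted p = 0.527, 0.945 and 0.818), though single members did. The response of Tyms differed by -3.02 ± 0.755 (SE, log2), that of the mitotic gene Tpx2 by -2.96 ± 0.806, that of Bard1 by -2.14 ± 0.542 and that of Tdg by -1.91 ± 0.53. Relb and the B cell lectin gene Siglecg gave -1.87 ± 0.459 and -1.86 ± 0.46, and Parp3 -1.46 ± 0.392. The largest falls were Mcf2l (-4.68 ± 1.06), Rims1 (-4.46 ± 1.01), Grhl3 (-4.46 ± 1.31) and Olfr1126 (-4.41 ± 1.03). The response was higher for Ccdc151 (4.83 ± 1.35), Psd3 (2.30 ± 0.502), the GTPase gene Rhob (2.28 ± 0.582), Meis1 (1.77 ± 0.525), Sirt5 (1.55 ± 0.42) and Lamp2 (1.11 ± 0.28). Chek1, Dnase1l3 and Kcng1 also passed with a lower and Slc8b1, Txnrd3, Aff4 and Apaf1 with a higher response, but each was well above background on no array of at least 1 of the 4 groups, so no value is given. Adjusted p ran from 0.0179 to 0.0475 over these genes. Platelet markers (median 0.64, adjusted p = 0.0359), antigen receptor signalling (0.48, 0.047) and apoptosis genes (0.41, 0.049) passed as lists, and none kept its call with an estimated correlation (adjusted p = 0.985). They lost their calls in 8, 10 and 13 of the 20 refits without 1 array (adjusted p up to 0.158, 0.133 and 0.133), each without the array labelled knockout 6 Gy replicate 1. Their medians were 0.81, 0.72 and 0.35 with slide (adjusted p = 0.0109, 0.00521 and 0.0575) and 1.32, 0.98 and 0.32 with scan day (adjusted p = 0.000114, 0.000114 and 0.24) as a fixed block.

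In all, 784 genes passed limma's threshold for the interaction at equal dose, 118 with a higher and 666 with a lower response in knockout blood, and 3330 had an unadjusted p under 0.05. The never-detected probes moved by -1.76, 59.3% of the falls were on probes not detected on every array against 41.8% of genes tested (Fisher's exact test, 1.6e-20), and over probes detected on all arrays 256 genes passed (44 higher and 212 lower). The split was 201 higher and 427 lower under quantile normalisation, 334 and 399 in the authors' table, which moved the median of all genes by 0.24, and 3510 and 431 under median centring, which moved it by 0.82. The sign of Apaf1 turned after normexp. With slide as a fixed block limma called 0 genes (542 at unadjusted p under 0.05) and with scan day 1, where the signs of Rims1 (0.69) and Slc8b1 turned. No slide or scan day held all 4 groups. Without the array labelled knockout 6 Gy replicate 1 the count was 1179 (137 higher and 1042 lower), and all 24 named genes passed. Leaving out 1 array gave from 24 genes (wild-type 6 Gy replicate 2) to 1440 (knockout 0 Gy replicate 1). Only Kcng1 and Dnase1l3 of the 24 named genes kept their calls in every refit, and the highest adjusted p of the others ran from 0.0593 (Psd3) to 0.0999 (Grhl3 and Txnrd3).

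For the interaction at equal lethality only the erythroid and ribosomal lists passed, with the preset correlation alone. Erythroid markers had a median of -0.75 (adjusted p = 5.99e-05, adjusted p = 0.914 with an estimated correlation), with Hemgn at -1.57 ± 0.494 (SE, log2) and Xpo7 at -1.04 ± 0.577 (adjusted p = 0.475 and 0.509), and the median was 0.00 after normexp. It was -0.86 with slide (adjusted p = 0.000118) and -0.01 with scan day (adjusted p = 0.368) as a fixed block. Ribosomal proteins had a median of 0.28 (adjusted p = 0.0228, adjusted p = 0.914 with an estimated correlation), with Rps27 at 0.64 ± 0.3 and Rps3 at 0.68 ± 0.377 (adjusted p = 0.475 and 0.509), and lost their call in 5 of the 19 refits without 1 array (adjusted p up to 0.117). Their median was 0.20 with slide (adjusted p = 0.0371) and 0.39 with scan day (adjusted p = 0.00899). By limma 0 genes passed, with 1352 at unadjusted p under 0.05 and a smallest adjusted p of 0.475, and an ordinary linear model also gave 0 (1291). Without the array labelled knockout 6 Gy replicate 1 the count was 0 as well (1748 at unadjusted p under 0.05) and the erythroid and ribosomal medians -0.87 and 0.37 (adjusted p = 7.84e-05 and 0.00175), while array weights gave 658 and normexp 6260. Median centring moved the median of all genes by 0.356 and the never-detected probes moved by -1.09.

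Probes of gene families can cross-hybridise with relatives, here Oas2, Oasl1, Oasl2, Ifit3b, Slfn4, Saa3, Ly6g, Ceacam10, Fcgr4, H2-Oa, H2-Ob, Hsp90ab1, Olfr1126, Bpifb9b and the ribosomal protein genes.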

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

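Dixon's test for 1 array apart from its group marks about 1 in 20 groups by chance. It marked 29 of 388 groups of named genes (19.4 by chance), 3 of 135 of list scores (6.75) and 4 of 35 of quality and tissue measures (1.75), and all these arrays were kept. Log2 levels in wild-type 0 Gy were -0.909 for Fcer1a, -1.4 for Mcpt8, -6.44 for Kcng1 and -3.68 for Oasl2 (replicate 1), 2.23 for Fcgr4 and -0.169 for Relb (replicate 3), and -0.902 for Oasl1 and 0.183 for Rtp4 (replicate 5). In wild-type 6 Gy they were -0.0517 for Ly6g (replicate 1), -4.31 for Pigg (replicate 2), -0.372 for Siglecf (replicate 3), and -2.41 for Casd1 and -1.84 for Txnrd3 (replicate 5). In wild-type 8.8 Gy they were -3.62 for Dapl1 (replicate 2), -5.32 for Gpr174, 3.16 for Oas2 and -1.13 for Siglecf (replicate 3). On the array labelled wild-type 8.8 Gy replicate 4 they were 0.779 for Hsph1, -3.95 for Parp1 and -0.94 for Vpreb3. In knockout 0 Gy they were -2.04 for Parp3 and 3.58 for Sirt3 (replicate 1), and -1.57 for Atpaf2, 3.51 for Mcf2l and -1.21 for Tdg (replicate 3). In knockout 6 Gy they were -3.38 for Kcng1 (the array labelled replicate 1), -1.26 for Pigg (replicate 2), 9.75 for Rps24 (replicate 3) and -0.605 for Tpx2 (replicate 5). Scores apart from their group were NAD metabolism 0.68 and NF-kappaB -0.437 (knockout 0 Gy replicate 1), antigen receptor signalling -0.723 (wild-type 6 Gy replicate 5), hepatocytes -1.73 and Kupffer cells -1.13 (wild-type 8.8 Gy replicate 1), and heart muscle -1.75 (wild-type 0 Gy replicate 1) and 2.87 (knockout 6 Gy replicate 3).

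Responses that differed between groups were the 784 genes of the interaction at equal dose, whose named members were Ccdc151 4.83, Psd3 2.30, Rhob 2.28, Meis1 1.77, Sirt5 1.55, Lamp2 1.11, Mcf2l -4.68, Rims1 -4.46, Grhl3 -4.46, Olfr1126 -4.41, Tyms -3.02, Tpx2 -2.96, Bard1 -2.14, Tdg -1.91, Relb -1.87, Siglecg -1.86 and Parp3 -1.46 (log2). Those well above background on no array of at least 1 group have no size and are given by adjusted p: Slc8b1 0.0347, Txnrd3 0.0463, Aff4 0.028 and Apaf1 0.0412 (higher response), and Dnase1l3 0.0179, Kcng1 0.0208 and Chek1 0.0336 (lower). As lists they were platelets 0.641, antigen receptor signalling 0.477 and apoptosis 0.406 at equal dose, and erythroid markers -0.747 and ribosomal proteins 0.277 at equal lethality. These include the array labelled knockout 6 Gy replicate 1.

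The spike-in control E1A_r60_1 read 9.05 to 9.59 on knockout 6 Gy replicates 2 to 4 and 18.2 to 19.0 on the other 21 arrays.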

How the results depend on the processing

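The settings in this part that leave out patches of spots, fit the hepatocyte score, leave out both doubted arrays or use scan day 3 alone were chosen after the first results were seen. Under the settings chosen beforehand 9 named gene and 12 list results reversed, and under those chosen later none.

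Counts of genes that moved, with the wild-type 6 Gy response first named W6, the 8.8 Gy response W8.8, the knockout response K6, the sham genotypes K0/W0, the genotypes at 6 Gy K6/W6, equal lethality K6/W8.8, the wild-type doses W8.8/W6 and the interactions ID (dose) and IL (lethality), were as follows. Quantile normalisation gave K0/W0 55, K6/W6 323 and W8.8/W6 136. Median centring gave W6 6094, K6/W6 3807, W8.8/W6 1688 and ID 3941. The percentile of detected probes gave K6/W6 965 and W8.8/W6 13. Normexp gave W6 1452, W8.8 4873, K0/W0 0, K6/W6 18, K6/W8.8 5747, W8.8/W6 2158, ID 0 and IL 6260, with an array SD of 1.15 in wild-type 8.8 Gy against 1.72 in wild-type 0 Gy arrays. The authors' table gave K6/W6 426 and W8.8/W6 139. Testing all genes without a filter gave W6 7025, K0/W0 30, K6/W6 620, K6/W8.8 1 and ID 7461. Fewer genes, on probes above background on all arrays, gave W6 1713, K6/W6 26 and ID 256. For K6/W6, testing every probe gave 315, the mean of probes 199 and a trend with a robust prior 62. Array weights gave W8.8 5184, K6 5806, K0/W0 2017, K6/W6 1047, W8.8/W6 1134, ID 2456 and IL 658. With only the groups compared, so fewer arrays, K0/W0 gave 26 and K6/W6 14. An ordinary linear model gave K0/W0 42 and ID 393.

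Slide as a fixed block gave W6 0, W8.8 0, K6 53, K0/W0 0, K6/W6 28, W8.8/W6 10 and ID 0, and as a random block K0/W0 0, K6/W6 587, W8.8/W6 9 and ID 90. Scan day as a fixed block gave W6 12, W8.8 23, K6 56, K0/W0 1, K6/W6 1, ID 1 and IL 1, and as a random block K0/W0 51. A fixed block leaves few arrays that link the groups. Beside the 0 counts, limma gave at an unadjusted p under 0.05 2665 (K0/W0) and 3752 (ID) with normexp. The replicate number as a block gave K0/W0 14, K6/W6 25 and ID 159, and of 10 pairs of groups 0 had every replicate pair correlated above 0.1 (-0.77 to 0.749), so this pairing was not used.

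The hepatocyte score as a covariate gave K0/W0 191, K6/W6 1397, W8.8/W6 592 and ID 1393. With this, the patches and the array labelled knockout 6 Gy replicate 1 left out, W8.8 gave 3417, K0/W0 218, K6/W6 1851, K6/W8.8 1, W8.8/W6 706 and ID 1983. Without both doubted arrays K0/W0 gave 40, K6/W6 606 and K6/W8.8 1, and scan day 3 alone gave K6/W6 1. With sham arrays split, 228.5 calls were shared by W6 and W8.8 instead of 1088, each part having fewer arrays.

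Leaving out 1 array gave 2258 to 3925 for W6, 1257 to 1979 for W8.8, 2351 to 3301 for K6, 1 to 353 for K0/W0, 0 to 534 for K6/W6, 0 to 0 for K6/W8.8, 0 to 6 for W8.8/W6, 24 to 1440 for ID and 0 to 0 for IL. Reversed lists, by the direction of the test, were under normexp W8.8 base excision repair (-0.0079), K6 ribosomal proteins (-0.0628) and oxidative phosphorylation (0.167), and W8.8/W6 p53 targets (-0.273), B cells (0.122), platelets (-0.135) and heat shock (-0.530). The base excision and ribosomal medians kept their sign, as did K0/W0 neutrophils with array weights (0.0882) and MHC class I with scan day fixed (-0.215). Also reversed were K0/W0 MHC class I with slide fixed (0.0237), neutrophils with scan day fixed (-0.369) and K6/W6 oxidative phosphorylation without knockout 6 Gy replicate 3 (-0.0872, and up to 0.384 without another array). Reversed genes were under normexp W8.8 Ccl3 (0.141), Epb4.2 (0.394) and Parp3 (0.411), K6 Rad51d (-0.0189) and ID Apaf1 (-0.134). With slide fixed it was W6 Ccdc151 (0.611), and with scan day fixed K0/W0 A4galt (-0.00135) and ID Rims1 (0.688) and Slc8b1 (-0.147). Except where the construction is named, the cause was not tested.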

Other observations

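The tests in this part were chosen after their results were seen, apart from the 9 counts under other splits of the arrays, the counts with scan day as a fixed block and those on always-detected probes. In 100 splits of the same arrays, counting the real one, a count as large came up 1 time, the least possible, in each response. These were wild-type 6 Gy (3433, highest other 840), 8.8 Gy (2089, 916) and knockout (2970, 290). Not adjusted for 9 counts, this argues against chance. The splits do not test scan day, which the groups follow. With scan day as a fixed block the counts were 12, 23 and 56 as the median SE of the called genes went from 0.348, 0.315 and 0.309 to 0.715, 0.635 and 0.59, while their median log2 change went from 1.29, 1.22 and 1.20 to 1.07, 1.10 and 1.13. The p53, interferon and B cell scores still differed in each response (adjusted p up to 0.0178), so scan day is unlikely to be their whole cause. The T cell score did not differ in all responses (adjusted p up to 0.213). Scan day stays open for these scores and for single genes. A count as large came up 4 times for the sham genotypes (88, 609) and 2 for the interaction at equal dose (784, 1114), under 5 in 100 but not adjusted for 9 counts and with higher counts in other splits, which argues only weakly against chance. It came up 5 times for the genotypes at 6 Gy (114, 1426), where chance cannot be excluded. The counts of 0 for equal lethality (highest other 805), the wild-type doses (338) and the interaction at equal lethality (1) are reached by all 100 splits whatever the data, so those tests decide nothing. Splits that call several times the real count point to a structure of the arrays other than the groups.

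The first pattern is the near-equal pair and the Parp1 levels against the labels. The same RNA on both arrays of that pair may explain a correlation of 0.0658 between probes of a gene. Their difference is then mostly noise. Different mice with like profiles are unlikely, as no other pair was below 0.207. Low Parp1 on the array labelled wild-type 8.8 Gy replicate 4 may come from a dim patch, as adding back the local deviation gives -1.97. Siglecf (0.787) argues weakly against knockout RNA, as genotypes overlap.

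The second pattern is liver RNA in blood. Tissue collected with the blood may explain it, as every hepatocyte marker had a within-group correlation with the others of at least 0.817. X rays or genotype are unlikely causes of the liver RNA, with a range of 9.96 within unirradiated wild-type arrays, and a different dim range is unlikely with a lung score range of 2.67.

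The third pattern is the falls in the interaction at equal dose and the rises at 6 Gy in wild type. A different dim range of the arrays may explain part, as 59.3% of those falls and 63.7% of those rises were on probes not well above background on every array. The 256 interaction calls on always-detected probes, and the count of 1 with scan day as a fixed block (median change 2.10 before and 0.94 after, median SE 0.549 and 1.07), leave dim range, scan day and biology such that they cannot be told apart.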
